A study of Mus musculus with 12 samples.

How the data were processed

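Testes of CD-1 mice at 1 and 4 days post partum (dpp) were lysed, and the cytoplasmic extracts were run on sucrose gradients that were collected in 14 fractions of 750 μl, per the labels. RNA pooled from fractions 1 to 3 is called non-translating here, and RNA pooled from fractions 7 to 13, the heavy polysomes, is called polysome. The fractions between them are in neither pool. Biotin-labelled antisense RNA was made from 5 μg of RNA and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. Each age and fraction pool has 3 arrays, 12 in all, and the labels call them biological replicates without saying which animals went into each, so the p-values measure the spread between these samples.

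The deposited values are probe set signal intensities on a linear scale, from 3.71 to 23370, and the submitters' processing notes name MAS5, with its version not given in the sources used here. The mean signal, trimmed by 2% at each end, ran from 106.5 to 147.2 between arrays, so how the arrays were scaled to each other is not known. Every array holds the same nominal amount of RNA, so a ratio of polysome to non-translating signal is relative to the other mRNAs of the same arrays and gives no share of an mRNA on polysomes. No raw array files were used here. The number of arrays limits the precision.

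Of 45101 probe sets, 64 are Affymetrix controls. Of the other 45037, 34945 have 1 gene symbol, 932 have several and 9160 have none in the platform annotation used here, and only those with 1 symbol were named. The Entrez ID of 34741 probe sets was found in the reference gene table, which changed 0 symbols. Signals were transformed to log2(value + 1), which understates the change of dim genes. Each gene was represented by its probe set with the highest mean signal, and genes below the 40th percentile of mean log2 signal over all probe sets other than controls (4.12) were left out, which left 13752 genes. One model with 4 groups was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on mean signal), and p-values were adjusted by the Benjamini-Hochberg method in each of 5 comparisons. These were polysome over non-translating at 1 dpp and at 4 dpp, 4 dpp over 1 dpp in the polysome and in the non-translating pools, and the change of the polysome ratio from 1 to 4 dpp as an interaction term. A gene is called when its adjusted p is under 0.05. All p-values are two-sided, and comparisons of single array measures used exact permutation tests, whose smallest possible p with 3 arrays against 3 is 0.1.

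Before the data were examined, 24 gene lists were fixed for translation, mitochondria, RNA classes, germ cell stages, somatic cell types of the testis, the cell cycle, extracellular matrix and stress. They were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list and with fry. None of the list calls (0 in each comparison) held with an estimated correlation, so every camera call in the text depends on the preset value. With fry, which tests whether a list moves on balance and does not compare it with other genes, 4 lists passed at 1 dpp and 3 between ages on polysomes, and 0 in the other comparisons. The rule for named genes was also fixed then. It takes, for each comparison, the 10 called genes with the largest change in each direction whose groups do not overlap (for the change of the ratio, without that condition), leaving out clone-like symbols. Where none is called in a direction, it takes the 5 with the smallest p, given as not passed. It adds up to 4 called members of each list described (otherwise the 2 brightest), and a fixed set of germ cell, somatic and reference genes. Of that set, Nanos2, Nanos3, Insl3, Ccnb1 and Gapdh have no probe set with a single symbol in the annotation used here and Xist did not pass the filter, so these 6 were not tested. Control probe sets gave the level of the spiked poly-A RNAs (12 probe sets) and the 3′ over 5′ signal of Actb and Gapdh on each array.

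The test was checked on simulated data drawn from the genes' means and spread, with 50 genes changed at each fold. Of 3-fold changes, 70% were called in the comparison of pools at 1 dpp, 72% at 4 dpp, 66% between ages in the polysome pools and 60% in the non-translating pools. For the change of the ratio, 20% of 3-fold and 0% of 2-fold changes were called. Each simulated comparison made 2 or 3 false calls. At 1 dpp 54% of 4-fold changes were called, fewer than of 3-fold ones, so 50 genes at each fold give a rough share. The simulated noise was independent between genes and equal on all arrays, so the false calls need not hold for the real arrays. Only 50 of 13752 genes were changed at each fold, and the cut-off after adjustment depends on how many genes change. The shares called need not hold where more genes change. Alternatives covered the scaling between arrays, the pseudocount, the filter, the choice of probe set, the variance model, the arrays in the fit, the replicate number as a block, a 2-fold threshold and leaving out each array. Further ones, with the spike level or 3′ bias as a covariate, the spike class as a block, or the polysome arrays that stood apart left out, were chosen after seeing the data.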

Results

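RNA pooled from the top of sucrose gradients, above the 80S ribosome peak, and RNA on heavy polysomes were profiled from neonatal mouse testes at 1 and 4 dpp, ages at which the germ cells leave their quiescent prospermatogonial state and become spermatogonia. The series title names the translational activation of developmental mRNAs over this interval. There are 4 groups of 3 arrays, the non-translating and the polysome pool at each age. Median signal was alike on all arrays, from 22.4 to 26.1, while the spiked poly-A RNAs differed. Their mean signal was 409.5 and 277.7 on 4 dpp polysome replicates 1 and 3 and 998.3 on 1 dpp polysome replicate 3, and from 2175 to 5887 on the other 9 arrays. The hybridisation controls were lowest on the same 3 arrays (1144, 986.9 and 1621, against 2567 to 4911 on the others). The trimmed mean signal was highest there (143.6, 147.2 and 136.4). A low spike level thus went with other measures of the whole array and does not mark the poly-A input alone. The 3′ over 5′ signal of Actb ran from 16.1 to 32.8 in the 1 dpp polysome group and from 4.48 to 6.78 in the 4 dpp polysome group. It was 84.1 on 4 dpp non-translating replicate 1, and from 7.07 to 14.5 on the other non-translating arrays. The mean 3′ minus 5′ log2 difference of Actb and Gapdh was 3.72 ± 0.70 (SD, n = 3) in the 1 dpp polysome group and 1.96 ± 0.26 (SD, n = 3) in the 4 dpp polysome group (exact permutation p = 0.1, the smallest possible).

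**Figure D1:**
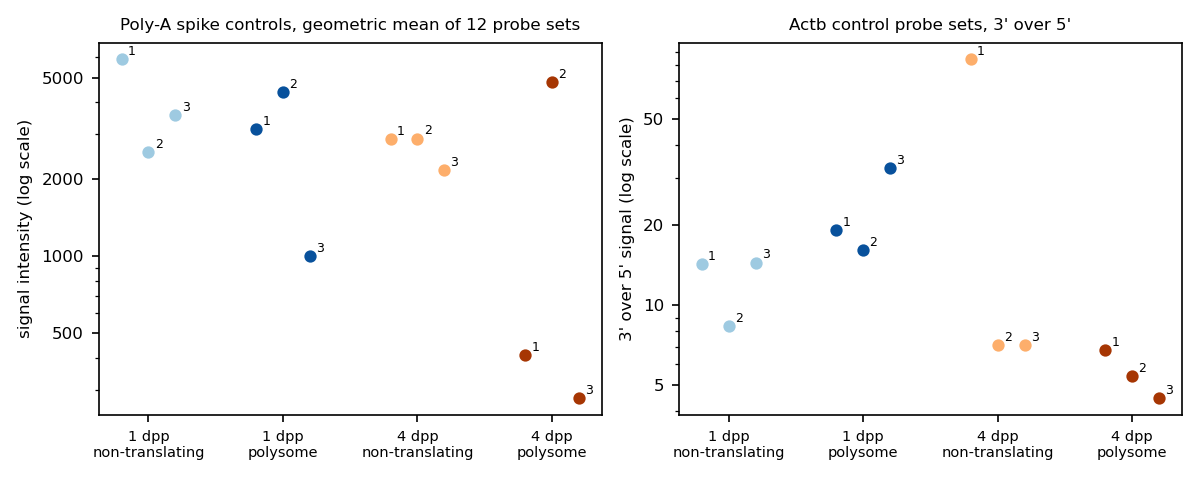
Signal of the spiked poly-A RNAs (left, geometric mean of 12 probe sets) and 3′ over 5′ signal of Actb (right) on each array, both on log axes, with the replicate number beside each point. The spike level is lowest on 4 dpp polysome replicates 1 and 3, at 409.5 and 277.7, and the 3′ over 5′ signal is highest on 4 dpp non-translating replicate 1, at 84.1.

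The first comparison asked which mRNAs were enriched on polysomes at 1 dpp. Tanc2, a scaffold protein of synapses, was 10.6-fold higher in the polysome pool (log2 3.40 ± 0.38, SE, n = 3, adjusted p = 0.000508), and Trim71, an RNA-binding ubiquitin ligase of stem cells and a target of the let-7 microRNA, 8.42-fold higher (3.07 ± 0.25, adjusted p = 0.000157). Slc44a2, Zbed6, Galnt2, Garem1, Clcn3, Kdm5a, Fbln7 and Tenm4 followed at log2 2.78 to 3.24. Among the lowest, Dancr was 13.6-fold lower on polysomes (−3.76 ± 0.54, adjusted p = 0.00142), Snhg4 had −3.48, the Gt(ROSA)26Sor transcript −3.22 and Snhg6 −3.01. Sp3, Nfkbiz, Col4a5, Ap3s1 and Mmd lay between −3.51 and −2.99. The mitochondrially encoded ND5, which is translated inside mitochondria, had −3.15.

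Among the fixed lists, ribosomal protein mRNAs and other 5′ terminal oligopyrimidine mRNAs were lower on heavy polysomes relative to other mRNAs. The fractions between the pools were not profiled and the length of reading frames was not taken into account. A low ratio therefore does not show by itself that an mRNA is translated less. Translation initiation and mTORC1 genes had 6 of 36 higher and 1 lower (7 and 2 adjusted over the list alone) and a median of 0.26, and did not pass (camera adjusted p = 0.211). Of 45 cytosolic ribosomal protein mRNAs, 22 were lower on polysomes, 0 higher and 23 not called (26 lower adjusted over the list alone), with a median of −0.51 and examples in Rpl22l1 (−2.22), Rpl14 (−1.73) and Rpl37 (−1.70). The list passed camera with adjusted p = 1.43e-11, and had adjusted p = 0.518 with an estimated correlation. Of 20 other mRNAs with a 5′ terminal oligopyrimidine tract, the element through which mTORC1 controls translation, 11 were lower and 1 higher (11 and 1 adjusted over the list alone), among them Naca (−1.79), Eif3h (−1.69) and Pabpc1 (−1.25). Their median was −0.71 (camera adjusted p = 5.81e-06, and adjusted p = 0.549 with an estimated correlation). Nuclear-encoded respiratory chain mRNAs had a median of −0.57, with 14 of 70 lower, led by the ATP synthase subunits Atp5g2 (−2.00), Atp5j (−1.93) and Atp5l (−1.74), and 2 higher (21 and 3 adjusted over the list alone; camera adjusted p = 1.19e-05, and adjusted p = 0.666 with an estimated correlation). Non-coding RNAs were lowest as a list, with a median of −1.37 and 16 of 24 lower (16 adjusted over the list alone), including Snhg12 (−2.44), Snhg5 (−2.38) and the imprinted Airn (−2.37). Their camera adjusted p was 3.77e-08, and adjusted p = 0.518 with an estimated correlation. Extracellular matrix mRNAs had 15 of 53 lower and 1 higher (15 and 2 adjusted over the list alone), with a median of −0.25. Examples are Col14a1 (−1.72), Col5a2 (−1.68) and Vcan (−1.67), and the camera adjusted p was 0.0344, and adjusted p = 0.695 with an estimated correlation.

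Cell type lists did not pass as lists, but single members did. Of 35 Sertoli cell genes, 5 were higher and 2 lower on polysomes (7 and 2 adjusted over the list alone, camera adjusted p = 0.357). Clu, a secreted chaperone, had 1.88 and Amh, the hormone that makes the Müllerian ducts regress, had 1.55, while the tight junction gene Tjp1 had −2.37. Of 33 genes of undifferentiated spermatogonia and prospermatogonia, 3 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.184), with the pluripotency factor Sall4 at 1.52 and Taf4b at 1.34. Of 23 spermatogonial differentiation genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.377). These were the cyclins Ccnd2 (1.70) and Ccnd1 (1.28) and the homeobox gene Rhox13 (1.25 ± 0.31, adjusted p = 0.0161), against Lmo1 (−1.69). The endothelial claudin Cldn5 had 1.88, the erythroid genes Tfrc and Alas2, for iron uptake and haem synthesis, had −2.54 and −2.19, and the macrophage receptor Mrc1 had −1.93. Asns and Creld2, targets of the integrated and endoplasmic reticulum stress responses, had 1.89 and 1.82. Kit (0.29), Stra8 (1.01), Sohlh1 (0.24), Sohlh2 (0.91), Dazl (−0.96) and Ddx4 (−0.29) were not called, with adjusted p from 0.0794 to 0.818.

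In all, 2621 of 13752 genes were called by limma, 1556 higher and 1065 lower on polysomes, of which 1893 changed at least 2-fold. The groups of 3 did not overlap for 41.3% of genes, against 10% by chance. Quantile normalization moved the balance to 1440 higher and 1529 lower (48.5% higher, against 59.4%). Leaving out a single array gave 1348 genes without polysome replicate 1, 1504 and 1545 without non-translating replicates 2 and 3 and 1626 without polysome replicate 2. The extracellular matrix list lost its call without 1 dpp non-translating replicate 3, 1 dpp polysome replicate 1 or 4 dpp non-translating replicate 1 (medians −0.20, −0.16 and −0.25, adjusted p = 0.11, 0.0654 and 0.0574). Of 50 called genes taken by the naming rule that have another probe set above the filter, 16 had the opposite sign on at least 1, among them Kdm5a (−1.47), Airn (1.33), Clcn3 (−0.18 and −0.56), Slc44a2 (−0.38), Vcan (0.24), Snhg5 (0.12) and Asz1 (0.13). Nfkbiz, Trim71 and Tanc2 had smaller values (−0.41, 0.76 and 0.44).

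The same question was asked at 4 dpp, where Tanc2, Zbed6 and Kdm5a were again among the 10 genes named highest. Tanc2 was 8.16-fold higher on polysomes (log2 3.03 ± 0.38, SE, n = 3, adjusted p = 0.00316), followed by Zbed6 (2.96), Ubn1 (2.72), the splicing factor Srrm2 (2.69), Prrc2c (2.59), Nol8 (2.56), Kdm5a (2.54), the transcriptional repressor Rest (2.51) and Map1b (2.48). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol in Leydig cells, was 5.51-fold higher (2.46 ± 0.49, adjusted p = 0.0106). The lowest were ND5 (−2.84), Clec2d (−2.78), Col4a5 (−2.70), Tbx3 (−2.53), Klk1b5 (−2.50), Dancr (−2.44), Bola3 (−2.44), Mmd (−2.43), Snhg6 (−2.41) and Nfkbiz (−2.33). Tex11, an X-linked meiotic recombination gene, was 4.16-fold higher on polysomes (2.06 ± 0.17, adjusted p = 0.000577), and Rhox13 3.37-fold higher (1.75 ± 0.31, adjusted p = 0.00712).

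Non-coding RNAs again had the lowest median, −1.34, with 13 of 24 lower (15 lower and 1 higher adjusted over the list alone), including Snhg8 (−2.19), Gas5 (−2.13) and Snhg12 (−2.10). They passed camera at adjusted p = 2.75e-07, and had adjusted p = 0.716 with an estimated correlation. Ribosomal protein mRNAs had a median of −0.28 and 2 of 45 lower (2 adjusted over the list alone), Rpl14 (−1.45) and Rpl22l1 (−1.19). Their camera adjusted p was 5.01e-05, and adjusted p = 0.716 with an estimated correlation. Other 5′ terminal oligopyrimidine mRNAs had 5 of 20 lower (6 adjusted over the list alone), among them Eif3h (−1.05) and Naca (−0.66), and a median of −0.41 (camera adjusted p = 0.0139, and adjusted p = 0.716 with an estimated correlation). Extracellular matrix mRNAs had 11 of 53 lower (12 lower and 1 higher adjusted over the list alone), led by the fibrillar collagen Col1a1 (−1.90) and by Vcan (−1.77) and Postn (−1.58). Their median was −0.16 (camera adjusted p = 0.0139, and adjusted p = 0.716 with an estimated correlation). RNA-binding regulators of translation had 8 of 52 lower and 4 higher (11 and 6 adjusted over the list alone), with Cnot7 (−1.32) and Zfp36l1 (−1.31) against Stau2 (1.40) and Khdrbs3 (1.31), and a median of −0.32 (camera adjusted p = 0.0334, and adjusted p = 0.716 with an estimated correlation). Immediate early genes had 3 of 25 lower (6 adjusted over the list alone), Ier3 (−1.72), Nr4a3 (−1.16) and Egr3 (−0.86), and a median of −0.30 (camera adjusted p = 0.0156, and adjusted p = 0.716 with an estimated correlation).

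A further 3 lists were higher on polysomes at 4 dpp, where 998 of all 13752 genes were called higher. Respiratory chain mRNAs had 10 of 70 higher (15 higher and 1 lower adjusted over the list alone), among them the ATP synthase subunit Atp5b (2.06), Uqcrc1 (1.97) and Sdhb (1.54), with a median of 0.25 (camera adjusted p = 0.0132, and adjusted p = 0.829 with an estimated correlation). Germ granule and piRNA pathway genes, which silence transposons in germ cells, had 3 of 27 higher (3 adjusted over the list alone), Stk31 (2.06), Asz1 (1.58) and Prmt5 (1.39). Their median was 0.42 (camera adjusted p = 0.0224, and adjusted p = 0.716 with an estimated correlation). Cell cycle genes had 3 of 47 higher, the replication helicase subunit Mcm6 (1.65), Kif20a (1.51) and Kif23 (1.06), and Hmmr lower at −1.02 (3 and 0 adjusted over the list alone). Their median was 0.55 (camera adjusted p = 0.0131, and adjusted p = 0.716 with an estimated correlation). The spike level was 409.5 and 277.7 on 4 dpp polysome replicates 1 and 3 and 4809 on replicate 2. With the arrays of low spike level as a block the medians of these lists were −0.05, −0.04 and 0.15 and their calls were lost (adjusted p = 0.538, 0.706 and 0.538). The calls of the ribosomal protein, other 5′ terminal oligopyrimidine and immediate early lists ended too (0.418, 0.149 and 0.164), with medians of −0.14, −0.48 and −0.41 under that block, so 3 of the 9 lists remained called. The mean 3′ minus 5′ log2 difference of Actb and Gapdh was 1.96 on the 4 dpp polysome arrays and 3.33 on the 4 dpp non-translating arrays, a difference of −1.36 (exact permutation p = 0.1, the smallest possible).

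In all, 1533 genes were called at 4 dpp, 998 higher and 535 lower, 1115 of them at least 2-fold. The groups did not overlap for 27.5% of genes, against 10% by chance. Quantile normalization moved the balance to 718 higher and 864 lower (45.4% higher, against 65.1%) and ended the ribosomal protein call (adjusted p = 0.199). Without a single array the count was 386 or 542 (non-translating replicates 2 and 3), 935 or 785 (polysome replicates 1 and 3) or 2793 (polysome replicate 2). Limma called 0 genes in a fit to these 6 arrays alone, where 2972 had an unadjusted p under 0.05. Leaving out single arrays also ended the calls of 5 lists (adjusted p from 0.0533 to 0.76). The respiratory chain median was 0.15 without non-translating replicate 3 and 0.02 without polysome replicate 1, and the germ granule median 0.36 without non-translating replicate 2 and 0.15 without polysome replicate 3. The other 5′ terminal oligopyrimidine list had −0.28 and −0.29 without non-translating replicates 2 and 3. The RNA-binding list had −0.22 and −0.13 without these and −0.33 and −0.08 without polysome replicates 1 and 2, and the extracellular matrix list −0.09 without polysome replicate 2. Of 39 called genes taken by the naming rule that have another probe set above the filter, 14 had the opposite sign on at least 1, among them Srrm2 (−0.98 and −1.27), Prrc2c (−0.62), Kdm5a (−0.37), Nol8 (−0.29), Stau2 (−0.19), Vcan (0.18), Hmmr (0.19), Egr3 (0.14) and Gas5 (1.14, against −1.97 on its brightest other one). Rest had 0.11, Ubn1 0.13 and Mmd −0.15 and −0.31 on other bright probe sets, and the dimmer ones of Cyp11a1 had 0.19 and −0.24.

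Across all 13752 genes the ratios at both ages had Pearson's r = 0.738 (across genes, which are not independent replicates), with no arrays shared between them. Of 3164 genes called at either age, 95.1% had the same sign at both, against 76.3% of all genes tested. Of the 3164, 624 were called higher at both ages and 364 lower at both, where independent lists would share 113.0 and 41.4. The ratio changed sides with calls at both ages for 2 genes, Tex11 and Asz1, from lower at 1 dpp to higher at 4 dpp, and for 0 genes the other way. The 1 dpp polysome signal of Tex11 was below the filter level (log2 4.12) on all 3 arrays, and raised to that level its 1 dpp ratio was −0.10. With a pseudocount of 64, 0 genes changed sides. In fits to the groups compared alone the count was also 0, but none was called at 4 dpp there, so it had to be. More genes changed sides without 4 dpp polysome replicate 2 or 1 dpp polysome replicate 3 and in the fits with the spike level, and fewer without 1 dpp polysome replicate 1, as given below.

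The change of the polysome ratio between ages was tested directly. Tex11 moved from −0.91 ± 0.17 at 1 dpp to 2.06 ± 0.17 at 4 dpp, a fitted log2 change of the ratio of 2.97 ± 0.25 (SE, n = 3 per group, adjusted p = 0.000455). Its signal was near the low end of the scale on the 1 dpp polysome arrays (log2 3.15 to 3.34) and rose to 7.11 to 7.29 on the 4 dpp polysome arrays, against 3.94 to 4.36 and 4.94 to 5.34 in the non-translating pools. Of its arrays 4 lay below the filter level of 4.12, and with these raised to that level the change of the ratio of Tex11 was 2.16, or 4.45-fold. Asz1, a germ granule protein of the piRNA pathway also known as Gasz, moved from −1.03 ± 0.24 to 1.58 ± 0.24, a 6.13-fold change (2.61 ± 0.33, adjusted p = 0.0266). Limma called these 2 genes of 13752, and 950 had an unadjusted p under 0.05, against 687.6 by chance. None was called lower, and the 5 with the smallest p in that direction were Sema4d (−1.48), Mmp17 (−1.43), Ngfr (−1.46), Rtn4rl1 (−1.53) and Actb (−0.98, with 0.86 on its other probe set), each with adjusted p = 0.66. The differentiation genes Kit (0.23), Stra8 (0.24), Sohlh1 (0.64), Sohlh2 (−0.45), Rhox13 (0.51), Dazl (0.57) and Ddx4 (0.84) were not called, with adjusted p from 0.779 to 0.981.

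In 6 lists the ratio shifted upward from 1 to 4 dpp. For respiratory chain mRNAs the median change was 0.83 and 66 of 70 members moved up, 0 of them called over all genes and 12 adjusted over the list alone (camera adjusted p = 2.23e-23, and adjusted p = 0.476 with an estimated correlation). Ribosomal protein mRNAs had a median change of 0.28 and other 5′ terminal oligopyrimidine mRNAs of 0.38, with 0 members called over all genes and 1 adjusted over the list alone in each. Their camera adjusted p values were 1.33e-06 and 0.000213, and adjusted p = 0.685 for both with an estimated correlation. Germ granule genes had a median of 0.52 with 1 of 27 called, Asz1 (1 adjusted over the list alone; camera adjusted p = 0.00175, and adjusted p = 0.762 with an estimated correlation). Cell cycle genes had a median of 0.36 (0 called, 0 adjusted over the list alone; camera adjusted p = 0.00492, and adjusted p = 0.762 with an estimated correlation) and macrophage genes of 0.27 (0 called, 0 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.685 with an estimated correlation).

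Across the same arrays the mean 3′ minus 5′ log2 difference of Actb and Gapdh, polysome minus non-translating, was 0.49 at 1 dpp and −1.36 at 4 dpp (exact permutation p = 0.6 and 0.1). At 1 dpp Actb alone had 0.85 and Gapdh alone 0.13 (exact permutation p = 0.1 and 0.9). With the middle probe sets in place of the 5′ ones the mean at 1 dpp was 0.65 (exact permutation p = 0.1). Germ granule and cell cycle genes lost their calls without 4 dpp polysome replicate 3 (medians 0.27 and 0.16, adjusted p = 0.0601 and 0.0844), and ribosomal protein mRNAs without 4 dpp polysome replicate 2 (0.16, adjusted p = 0.086). Macrophage genes lost theirs without 1 dpp non-translating replicate 1, 1 dpp polysome replicate 3 or 4 dpp non-translating replicate 3 (medians 0.36, 0.61 and 0.17, adjusted p = 0.0955, 0.0749 and 0.138) and with the filter at the 60th percentile (0.48, adjusted p = 0.052). Other 5′ terminal oligopyrimidine mRNAs lost theirs with the 3′ to 5′ covariate (0.11, adjusted p = 0.274). Without the 2 polysome arrays whose spike level lay apart from their group, 3 of the 6 lists remained called, and the ribosomal protein, other 5′ terminal oligopyrimidine and macrophage lists had medians of 0.12, 0.52 and 0.94 (adjusted p = 0.641, 0.105 and 0.0566). In that fit age and spike level are confounded. Asz1 lost its call under scaling to the median, quantile normalization, a pseudocount of 64, every probe set and the replicate block, with the 3′ to 5′ difference as a covariate, and without any 1 array except 4 dpp non-translating replicate 3 and 4 dpp polysome replicate 1 (adjusted p from 0.0506 to 0.405). Tex11 kept its call under every alternative in which it was tested, and lay below the filter at the 60th percentile. The dimmer of the 2 Asz1 probe sets (mean log2 4.39) gave 0.13 at 1 dpp and 0.52 at 4 dpp.

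The abundance of mRNAs on polysomes was then compared between ages. Car3, a carbonic anhydrase of muscle and fat cells, was 17.0-fold higher at 4 dpp (log2 4.09 ± 0.63, SE, n = 3, adjusted p = 0.0172), Tex11 at least 8.48-fold with its 1 dpp signal raised to the filter level (fitted log2 3.96 ± 0.17, adjusted p = 2.56e-07) and Asz1 10.6-fold (3.40 ± 0.24, adjusted p = 2.96e-05). Snrpd3, a core spliceosomal protein, had 3.08, Tmbim4 2.76, Cox7b2 2.61, the fat cell lipid carrier Fabp4 2.56, Ndufa4 2.46, Atp23 2.43 and Smim8 2.34. Lower at 4 dpp were Pnmt, which makes adrenaline from noradrenaline (−2.20 ± 0.35, adjusted p = 0.0172), St8sia2 (−2.06), the apelin receptor Aplnr (−2.04), Pcdh9 (−2.04), the heparan sulfate proteoglycan Gpc1 (−2.00 ± 0.23, adjusted p = 0.00468), Thy1 (−1.93), Lin7a (−1.89), Mmp16 (−1.83), Itga4 (−1.78) and Pigt (−1.77).

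Of the germ cell lists, 3 were higher on polysomes at 4 dpp. Of 27 germ granule and piRNA genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone), with the Tudor domain genes Rnf17 (1.78) and Tdrkh (1.34) and the intercellular bridge gene Tex14 (1.59) beside Asz1. Their median was 0.86 (camera adjusted p = 6.71e-07, and adjusted p = 0.644 with an estimated correlation). Of 23 spermatogonial differentiation genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone). These were Nxf2 (1.80), Rhox13 (1.69 ± 0.31, adjusted p = 0.0173), Sox3 (1.55) and Lmo1 (2.84-fold higher), and Ccnd2 (−1.25, with 0.55 on 1 of its 6 other probe sets), which was named after its values were seen. The median was 0.73 (camera adjusted p = 0.0116, and adjusted p = 0.644 with an estimated correlation). Of 23 meiosis genes, 2 rose, Tex11 and the meiotic cohesin subunit Stag3 (1.89), or 7 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.000116, and adjusted p = 0.393 with an estimated correlation). Undifferentiated spermatogonia and prospermatogonia genes had a median of −0.26, with 1 of 33 higher and 3 lower (2 and 8 adjusted over the list alone), and spermatid genes −0.06, and neither list passed (camera adjusted p = 0.218 and 0.935). Stra8 (1.63, adjusted p = 0.0597), Ddx4 (2.11, adjusted p = 0.0567), Dazl (2.07, adjusted p = 0.15), Kit (0.89), Sohlh1 (0.56) and Sohlh2 (0.73) were not called.

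Respiratory chain mRNAs rose as a list, with 25 of 70 higher and 0 lower (48 and 0 adjusted over the list alone) and a median of 0.96. Examples are the complex I subunits Ndufa4 (2.46), Ndufab1 (2.31) and Ndufs4 (1.99) and Atp5l (1.92). Their camera adjusted p was 2.42e-19, and adjusted p = 0.644 with an estimated correlation, and fry gave 0.0312. Ribosomal protein mRNAs had 6 of 45 higher (10 adjusted over the list alone), such as Rps27l (1.26) and Rpl22l1 (1.21), with a median of 0.22 (camera adjusted p = 0.000213, and adjusted p = 0.644 with an estimated correlation). Other 5′ terminal oligopyrimidine mRNAs had 3 of 20 higher (3 adjusted over the list alone), Naca (1.31), Eif3h (0.94) and Eef1b2 (0.60), with a median of 0.31 (camera adjusted p = 0.00734, and adjusted p = 0.644 with an estimated correlation). Cell cycle genes had Kif20a (1.95) and the replication clamp Pcna (1.62) higher and Tyms (−0.83) lower (3 and 1 adjusted over the list alone) among 47, with a median of 0.44 (camera adjusted p = 0.00373, and adjusted p = 0.644 with an estimated correlation). Between the same arrays, the 3′ minus 5′ log2 difference of Actb and Gapdh was −1.75 for 4 dpp minus 1 dpp (exact permutation p = 0.1). Of the somatic lists none passed, with camera adjusted p = 0.995 for Sertoli cell, 0.935 for Leydig cell (median 0.05, test direction down), 0.907 for peritubular myoid, 0.0893 for endothelium, 0.218 for macrophage and 0.662 for erythrocyte genes. Endothelial Cldn5 (−1.34), Plvap (−1.27) and Flt1 (−0.95) fell, 3 of 20 (6 adjusted over the list alone), where 7% of all genes were called. The cell cycle inhibitor Cdkn1a had −1.24 (0.14 on its other probe set), and Actb −0.96 (0.77 on its other probe set).

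In all, 963 genes were called between ages on polysomes, 468 higher and 495 lower at 4 dpp, 722 of them at least 2-fold, and the groups did not overlap for 23.3% of genes against 10% by chance. The count was 3 without 1 dpp polysome replicate 1 or 2, 7 without 4 dpp polysome replicate 1, 3255 without 4 dpp polysome replicate 2, 2132 without 1 dpp polysome replicate 3, 598 without 4 dpp polysome replicate 3, 369 to 571 without single non-translating arrays except 4 dpp replicate 1, 2 in a fit to these 6 arrays alone (2711 at an unadjusted p under 0.05) and 221 with the 3′ to 5′ difference as a covariate. The balance was 532 higher and 1233 lower with the spike level as a covariate (30.1% higher, against 48.6%), and 3609 and 2217 (61.9%) without the 2 polysome arrays whose spike level lay apart. Quantile normalization ended the calls of the ribosomal protein and the other 5′ terminal oligopyrimidine lists (adjusted p = 0.0548 and 0.0745), as did leaving out 4 dpp polysome replicate 2 (0.276 and 0.221). The ribosomal protein list also lost its call without 1 dpp polysome replicate 3 (median 0.20, adjusted p = 0.0576), and the spermatogonial differentiation list without 4 dpp polysome replicate 3 (0.36, adjusted p = 0.0501). Car3, Ndufa4 and Rhox13 lost their calls without 1 dpp polysome replicate 1 or 2 or 4 dpp polysome replicate 1 (adjusted p from 0.0719 to 0.104). Of 33 called genes taken by the naming rule that have another probe set above the filter, 11 had the opposite sign on at least 1, among them Snrpd3 (−0.86 and −0.35) and Car3 (−0.02). A dim probe set of Tmbim4 had −0.02.

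**Figure D2:**
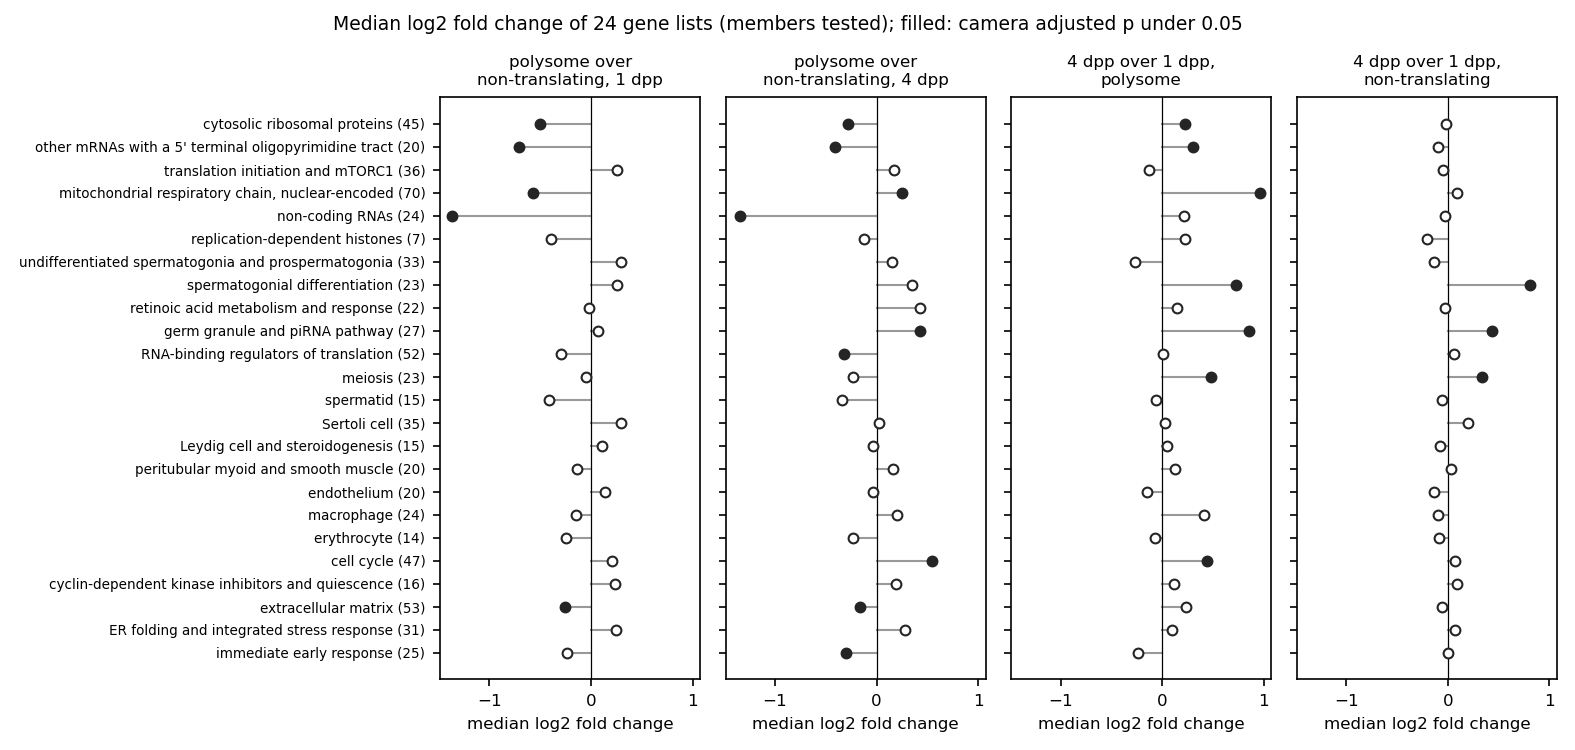
Median log2 fold change of each of 24 gene lists (number of members tested in brackets) in 4 comparisons; filled circles passed camera with the preset correlation at an adjusted p under 0.05. Respiratory chain mRNAs had −0.57 at 1 dpp and 0.25 at 4 dpp, and 0.96 between ages on polysomes against 0.09 in the non-translating pools.

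In the non-translating pools 1 gene was called between ages. Car3 was 55.7-fold higher at 4 dpp (log2 5.80 ± 0.63, SE, n = 3, adjusted p = 0.00998), at 10.6 to 11.2 on the 4 dpp arrays against 4.07, 4.44 and 7.00 on the 1 dpp arrays. Its fold was 55.1 with signals below the filter level raised to it, and the other 3 probe sets of Car3 had 2.00, 1.79 and 1.45 on the log2 scale. Limma gave 591 genes an unadjusted p under 0.05, below the 687.6 that chance gives, and the groups did not overlap for 14.7% of genes against 10% by chance. That fit shares 1 spread between all 4 groups. The lowest r between arrays of a group was 0.886 and 0.923 in the polysome groups, and 0.939 and 0.957 in the non-translating ones. The 591 depends on this shared spread and does not show that the non-translating pools differ less than by chance. In a fit to these 6 arrays alone 1199 genes had an unadjusted p under 0.05. The 963 genes called between ages on polysomes rest on the same shared spread. The counts of 963 and 1 therefore do not measure how far the pools differ in their change with age. Of genes lower at 4 dpp none was called, and the smallest p values belonged to Tm4sf5 (−0.99), Stfa3 (−1.40), Tmem59l (−1.12), the chemokine Ccl17 (−1.94) and the neutrophil gene S100a8 (−1.52), with adjusted p from 0.228 to 0.32. The same 3 germ cell lists were higher here, with 0 members called over all genes in each, while undifferentiated spermatogonia and prospermatogonia genes had −0.13 and spermatid genes −0.06 (camera adjusted p = 0.655 and 0.547). Spermatogonial differentiation genes had a median of 0.81 and 9 of 23 higher adjusted over the list alone (camera adjusted p = 4.87e-06, and adjusted p = 0.393 with an estimated correlation). Meiosis genes had a median of 0.34 and 2 of 23 (camera adjusted p = 1.19e-06, and adjusted p = 0.124 with an estimated correlation), and germ granule genes 0.43 and 2 of 27 adjusted over the list alone (camera adjusted p = 2.09e-05, and adjusted p = 0.636 with an estimated correlation). Respiratory chain and ribosomal protein mRNAs had medians of 0.09 and −0.02 (camera adjusted p = 0.281 and 0.74). Car3 lost its call without 1 dpp replicate 2 or 3 or any 4 dpp non-translating array (adjusted p from 0.065 to 0.137) and in a fit to these 6 arrays alone (0.0711).

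The genes called between ages on polysomes moved the same way in the non-translating pools more often than not. These comparisons share no arrays, but the labels leave open whether the pools of an age share animals. The share over all genes is not given here. Of 468 higher on polysomes at 4 dpp, 87.8% were also higher in the non-translating pools, with a median of 1.43 on polysomes and 0.30 in the non-translating pools. Of 495 lower genes, 91.7% were also lower, with medians of −1.06 and −0.31. Of the 468, 175 had been called lower on polysomes at 1 dpp and 3 higher, and of the 495, 325 higher and 2 lower. That ratio shares the 1 dpp polysome arrays with the age comparison.

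**Figure D3:**
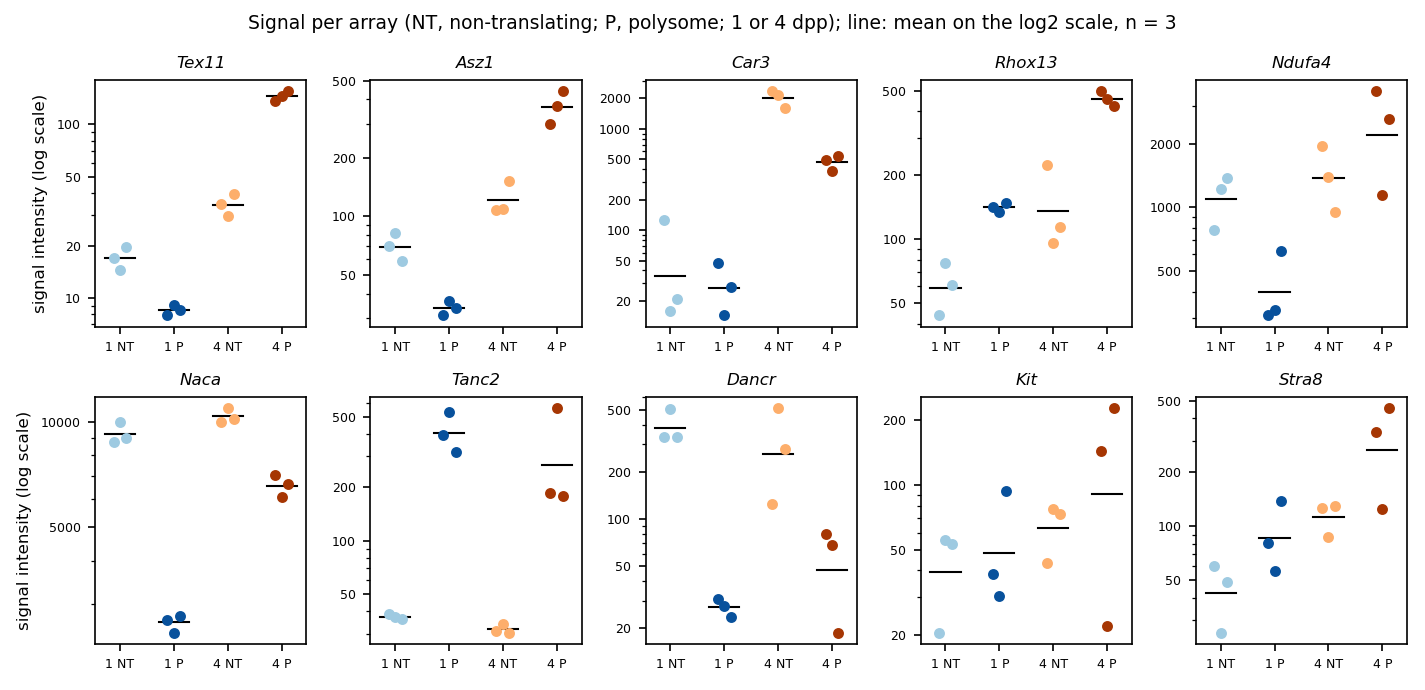
Signal intensity (log axis) of 10 genes on each array of the non-translating (NT) and polysome (P) pools at 1 and 4 dpp, with a line at the mean on the log2 scale (n = 3). Asz1 lies lower on polysomes at 1 dpp and higher at 4 dpp, Tex11 lies higher on polysomes at 4 dpp and below the filter level on the 1 dpp polysome arrays, and Car3 was called between ages in both pools.

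Of the remaining lists and the spermatid list, none passed camera in any of the 5 comparisons. At 1 dpp the medians of the polysome ratio were −0.40 for replication-dependent histones (camera adjusted p = 0.0672, while fry gave 0.00921), −0.02 for retinoic acid metabolism (0.602; their mean of 0.20 has the other sign), −0.41 for spermatid (0.0755), 0.23 for cyclin-dependent kinase inhibitors and quiescence (0.904; their mean of −0.07 has the other sign) and 0.25 for endoplasmic reticulum folding and stress genes (0.378).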

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

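The carry-over and exchanged-label tests, and the fits with a spike or 3′ covariate or block, were chosen after the results were seen.

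The polysome ratio differed between ages, by the interaction term, for Tex11 (2.97) and Asz1 (2.61) and, as list medians, for ribosomal proteins (0.275), other 5′ terminal oligopyrimidine mRNAs (0.381), respiratory chain mRNAs (0.828), germ granule genes (0.523), macrophage genes (0.268) and cell cycle genes (0.363). With an estimated correlation camera called none of these 6 lists (adjusted p from 0.476 to 0.762), and with signals raised to the filter level the change of Tex11 was 2.16. Of 100 splits with ages permuted within each pool, the real one included, 7 gave at least 2 genes (highest other 3172). Of the same 100, 37 gave at least 6 lists (highest other 14), so chance was not excluded for either count. A split with 3172 genes points to a structure of the samples. For the 2 genes called on opposite sides of the ratio, 2 of 100 splits of the fraction labels, the real one included, gave at least 2 (highest other 988, with the labels of 1 age turned over). The remaining 98 splits gave 0, since mixed labels leave almost no calls at either age, so this comparison decides nothing about that count.

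The comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. The number of splits in brackets is of those that gave at least the real count, and it includes the real split. For polysome over non-translating, the real split gave 2621 genes at 1 dpp and the highest other 0 (1 split as large), and at 4 dpp 1533 and 1 (1 split). Between ages it gave 963 on polysomes and 5116 (2 splits), and 1 in the non-translating pools and 0 (1 split). For lists the real and highest other counts were 5 and 10 (5 splits), 9 and 11 (2 splits), 7 and 9 (5 splits) and 3 and 11 (6 splits), in the same order. The split with 5116 genes parted 1 dpp polysome replicates 1 and 2 and 4 dpp polysome replicate 2 from the 3 arrays of low spike level, which points to a structure of the samples, and with that class as a block 1749 genes were called between ages.

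The first pattern weighed is the set of 963 genes called between ages on polysomes. For these genes the trend of the spike level within groups predicted a median share of 0.164 of the change (quartiles 0.0362 and 0.267). They were called against a spread that includes this trend. Genes that follow the spike level closely were thus less likely to be among them. The low share therefore does not show how far the spike level accounts for the set. For the 3′ bias the share was −0.0669, and −0.318 without 4 dpp non-translating replicate 1. The 3′ to 5′ difference did not overlap between the ages on polysomes, so a trend within groups cannot part it from age. With the 3′ to 5′ difference as a covariate the median size went from 1.23 to 1.30 and the SE from 0.277 to 0.352, and the calls fell to 221 because the error grew. Exchanged labels of 1 dpp polysome replicate 3 and 4 dpp polysome replicate 2 were weighed with an age score. It was made from the 100 genes with the smallest p between ages in the non-translating pools. The lowest 4 dpp polysome score lay 0.61 above the highest 1 dpp one, on the side of the given labels. The spread behind those p-values includes the polysome arrays under these labels, so the choice of genes was not independent of them and the gap does not settle the point. Age stays open as a biological explanation that the design names, as do the 3′ bias and the spike level.

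The second pattern is the higher respiratory chain list on polysomes at 4 dpp. Carry-over of non-translating RNA into 4 dpp polysome replicates 1 and 3 would draw the list's ratio towards 0. That ratio was 0.909 on replicate 1 and 0.279 on replicate 3 (SD 0.196 between non-translating arrays). How the arrays were scaled to each other is not known. The trimmed mean signal was 147.2 on replicate 3, against 111.1, 123.5 and 126.1 on the 4 dpp non-translating arrays. An offset of the whole array could lift a ratio above 0, so 0.279 does not exclude carry-over into replicate 3. The trends within groups predicted shares of 0.226 for the spike level and −0.274 for the 3′ bias (−0.542 without 4 dpp non-translating replicate 1). Carry-over into 4 dpp polysome replicate 2 also stays open and may account for its ratio of −0.152, with non-coding RNAs at −0.631, the nearest to 0 of the polysome arrays. Within the spike classes, the list's 4 dpp minus 1 dpp median was 0.901 (2 arrays against 1) and 0.695 (1 against 2). A change with age stays open, as does the 3′ bias, which differed between the ages.

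The third pattern is that 2 genes were called for the change of the ratio. Spread that follows the spike level stays open as a reason for so few. With it as a covariate 2 genes were called, but those with an unadjusted p under 0.05 went from 950 to 2032 (1629 with the spike class as a block), so the adjusted count, which had been set in advance as the deciding value, was too coarse to decide. The test called 0% of simulated 2-fold changes of the ratio. Few genes were changed in that simulation, and the cut-off after adjustment depends on how many change. The 0% therefore does not give the share that would be called in these data. Too few arrays for changes of this size stays open as a reason. No biological explanation was tested.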

How the results depend on the processing

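The fits with the spike level or the 3′ to 5′ difference as a covariate, with low spike level as a block, and without 1 dpp polysome replicate 3 and 4 dpp polysome replicate 2 were chosen after seeing the data, and the cause of the shifts below was not tested unless given. Of 458 named gene results, 431 kept direction and side of the threshold with arrays centred on their median, 435 with quantile normalization, 455 with a pseudocount of 16, 425 without a filter, 376 with the 3′ to 5′ covariate and 345 to 440 without single arrays. In fits to the groups compared alone, 232 of 389 did.

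Every probe set, which tests more features, gave 4298 calls at 1 dpp, 2769 at 4 dpp and 1 for the change of the ratio. Fits to the groups compared alone used the spread of those groups, estimated from fewer arrays. They gave 3164 at 1 dpp and 0 at 4 dpp. Between ages they gave 2 on polysomes and 0 in the non-translating pools, and 0 genes lay on opposite sides. Genes with an unadjusted p under 0.05 rose from 4610 to 5056 at 1 dpp and from 591 to 1199 in the non-translating pools. They fell from 3795 to 2972 at 4 dpp and from 3681 to 2711 between ages on polysomes. Fewer arrays alone thus do not account for all these shifts. In the non-translating pools, pseudocounts of 16 and 64 gave 2. The change of the ratio had 1 gene with arrays centred on their median, quantile normalization, a pseudocount of 64, the filter at the 60th percentile (which removed Tex11) and the 3′ to 5′ covariate. Opposite sides had 0 with a pseudocount of 64 and 1 at least 2-fold.

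With the spike level as a covariate the counts were 5278 at 1 dpp, 3554 at 4 dpp, 1765 and 17 between ages on polysomes and in the non-translating pools, and 15 on opposite sides. With low spike level as a block they were 4864, 2967, 1749, 3 and 6. Without the 2 polysome arrays whose spike level lay apart they were 4147, 3875, 5826, 3 and 136, and 1517 for the change of the ratio. That leaves polysome arrays of high spike level at 1 dpp and of low spike level at 4 dpp, so age and spike class cannot be told apart in the counts of 5826, 136 and 1517. The 3′ to 5′ covariate gave 221 between ages on polysomes.

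With the replicate number as a block, 603 genes were called at 4 dpp and 1 for the change of the ratio. The labels do not say that equal numbers share a gradient, and the deviations of arrays with the same number within an age correlated across genes from −0.558 to 0.6, so the numbers were not used to pair the samples.

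Lists past the threshold with an estimated correlation were 0 in each of 5 comparisons. With fry they were 4 at 1 dpp (ribosomal proteins, other 5′ terminal oligopyrimidine mRNAs, non-coding RNAs and, not called by camera, histones), 0 at 4 dpp, 3 between ages on polysomes, 0 in the non-translating pools and 0 for the change of the ratio. With the spike covariate they were 3 at 4 dpp and 5 in the non-translating pools, and with the spike block 3 at 4 dpp. The direction of the set test turned for 0 called lists under the alternatives run, but the medians of the respiratory chain and germ granule lists at 4 dpp turned to −0.05 and −0.04 with the spike block, where neither was called.

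Without single arrays, counts ran from 1348 to 3494 at 1 dpp, from 386 to 2793 at 4 dpp, from 3 to 3255 between ages on polysomes, from 0 to 2 in the non-translating pools (0 without 1 dpp replicate 2 or 3 or any 4 dpp replicate of that pool, 2 without 1 dpp polysome replicate 2), from 1 to 2 for the change of the ratio and from 1 to 8 on opposite sides (1 and 4 without 1 dpp polysome replicates 1 and 3, 8 without 4 dpp polysome replicate 2). List counts ran from 4 to 6, 6 to 9, 5 to 8, 3 to 4 and 5 to 8. For the change of the ratio, 4 of the 6 lists stayed called without 4 dpp polysome replicate 3, at least 5 without any other single array, and 3 without the 2 polysome arrays whose spike level lay apart. The 3′ minus 5′ difference ran from 0.09 to 0.75 for polysome over non-translating at 1 dpp, from −1.84 to −0.435 at 4 dpp, from −2.02 to −1.35 between ages on polysomes and from −0.829 to 0.573 in the non-translating pools.

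Leaving out probe sets that end in _x_at, _s_at or _a_at, so that another probe set stands for the gene, turned the polysome ratio of Clcn3 (−0.18), Eif6 (−0.16) and Cald1 (1.32) at 1 dpp and of Eif6 (−0.17), Gas5 (1.14), Stau2 (−0.19), Cald1 (1.75) and Acta2 (−0.82) at 4 dpp, and the age difference on polysomes of Ptgds (0.23) and Mcl1 (0.71). With the spike covariate Kit had −0.82 at 4 dpp, where it was 0.52 and not called.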

Other observations

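At 4 dpp the lists of endoplasmic reticulum folding, Sertoli cell and quiescence genes did not pass as lists, with single members called, where 11.1% of all genes were. Creld2 (2.25) and Dnajc3 (1.96), which act in folding in the endoplasmic reticulum, were called higher on polysomes, 3 of 31 in their list with Asns (1.31) and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.285 by limma). Of 35 Sertoli cell genes 2 were higher, Clu (1.40) and Ptgds (1.46), and 2 lower, with Tjp1 at −1.83 (2 and 2 adjusted over the list alone, camera adjusted p = 0.691). The cell cycle inhibitor Cdkn1b had −1.31, in a list with 1 of 16 higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.691) whose median of 0.19 and mean of −0.04 differ in sign.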
